A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

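The libraries were made from polyadenylated RNA of exponentially growing wild-type and nhp6ab yeast, 2 libraries each, grouped by the titles in the labels. RNA was extracted with phenol and chloroform and made into Illumina libraries, per the labels' protocols. The authors deposited a table of RSEM expected counts per gene and a table of RSEM TPM values, both named so by the deposited sheets. The genome build was sacCer3, per the submitters' processing notes. The aligner, the RSEM version, the gene annotation and whether the counting used strand are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene may have been mixed. RSEM divides reads that fit several genes among them by estimate, so values of near-identical genes are uncertain. The deposited expected counts summed to 22622592 to 29115870 per library. The deposited TPM values are scaled for length and library total, and they were used only for an alternative.

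The table held 6688 gene identifiers and 4 lines without an identifier, which were left out. Of the identifiers, 6005 matched the RefSeq annotation of the R64 reference, which gave symbols and coordinates, and 683 did not match and kept their identifiers. The unmatched ones held 1.54 to 1.95% of counts. The deposited tables hold no coordinates, and those printed are of R64. Genes were marked as having a near-identical copy where BLAST+ 2.17.0 aligned at least 50% of the coding sequence at 95% identity or more, which applied to 340 genes. The coding sequences of NHP6A and NHP6B are 77.9% identical over 263 bases.

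Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, the default low-count filter with a minimum count of 10 and a minimum total of 15, quasi-likelihood F test, strain as the only term, 2 residual degrees of freedom). P-values were adjusted by Benjamini and Hochberg over the 6422 genes that passed the filter, and a gene was called at an adjusted p under 0.05. The TMM factors were 0.924 and 0.934 in the wild type and 1.06 and 1.10 in nhp6ab. CPM values use these factors. Standard errors are the size of the log2 fold change divided by the square root of F. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and adjusted over 35 lists with at least 3 tested members. In all, 1 list was called higher and 8 lower, and a list is said to be called by this test unless another is named. With an estimated correlation 0 were called (smallest adjusted p = 0.70). That form of the test rests on the 2 residual degrees of freedom, so it has little power here. The stress, iron and remodeller lists had estimated correlations of -0.018, 0.00055 and 0.0074, below the preset 0.01, and lost their calls too. Correlation alone therefore does not account for the loss. Fry, which tests whether the members of a list move one way on balance, called 4 higher and 14 lower.

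The 35 lists, the groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took NHP6A and NHP6B, the 12 largest increases and the 12 largest decreases among called genes with a mean of at least 5 CPM and both nhp6ab libraries on the same side of both wild-type libraries, up to 4 called members of each list with the smallest adjusted p (or, where none was called, up to 2 with the smallest unadjusted p), and every core histone gene, locus studied for Nhp6 or FACT, a-specific or alpha-specific gene and marker gene. It gave 163 genes. Genes added to it are named as such.

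The test was tried on simulated counts for 6406 genes with the means, depths and gene-wise dispersions of these libraries. It found 33 of 50 genes changed 1.3-fold, 44 of 50 changed 1.5-fold, 49 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 11 false calls. Far fewer genes were changed in it than the 49.5% called in the data. The adjusted p depends on that share, so these rates do not carry over to the data. In the simulated lists, the 1 shifted list was found with the preset correlation, 0 other lists were called, and with an estimated correlation 0 were found, so the estimated correlation missed the simulated shift. The simulated genes were drawn independently, whereas the correlation estimated in the called lists ran from -0.018 (stress) to 0.39 (Gcn4). The simulation therefore cannot show how the preset correlation performs where genes vary together.

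Alternatives were DESeq2 1.42.0 and its size factors, upper quartile factors, library size alone, TMM without ribosomal protein genes, no low-count filter, a filter of 10 CPM in 2 libraries, limma-voom, a robust fit, unrounded counts, limma on log2(TPM + 1) and log2(TPM + 0.1), a replicate term, and each library left out in turn. Random matched lists and figures used R and Python 3.11.15 with matplotlib 3.10.9.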

Results

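The series holds polyadenylated RNA from budding yeast, Saccharomyces cerevisiae, grown exponentially in YPD, a rich glucose medium. It compares wild-type cells with the nhp6ab strain, the usual name for a strain that lacks both NHP6A and NHP6B. These genes encode closely related small proteins with an HMG box, a domain that bends DNA, and the proteins act together with the histone chaperone FACT (Spt16 and Pob3). There were 2 libraries per strain. The deposited expected counts summed to 27581468 and 22622592 in the wild-type libraries and to 29115870 and 28721743 in the nhp6ab libraries. Over 6422 genes tested, the Pearson correlation of log2(CPM + 1) was 0.997 between the wild-type libraries, 0.996 between the nhp6ab libraries and 0.974 to 0.978 across strains. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 24.7 in the wild type and 22.4 in nhp6ab. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Without a spike-in, all changes are relative to the rest of the transcriptome.

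NHP6A and NHP6B were both lower in the nhp6ab libraries, by very different amounts. NHP6A (YPR052C; chromosome XVI, 665693 to 665974, minus strand, 1 exon) had 122 and 130 CPM in the wild type and 11.1 and 12 CPM in nhp6ab. It kept 9.18% of its wild-type level (log2 fold change -3.44 ± 0.07 SE, adjusted p = 1.05e-06 in edgeR). NHP6B (YBR089C-A; chromosome II, 426190 to 426489, minus strand, 1 exon) had 80.0 and 86.0 CPM in the wild type and 33.4 and 32.6 CPM in nhp6ab. It kept 39.8% of its wild-type level (log2 fold change -1.33 ± 0.06 SE, adjusted p = 1.35e-05). Both genes share bases with another open reading frame on the same strand, so their counts are uncertain. YPR053C, which overlaps NHP6A, fell from 71.0 ± 4.24 to 2.84 ± 0.07 CPM (SD, n = 2 each), and YBR090C, which overlaps NHP6B, fell from 45.2 ± 4.27 to 19.6 ± 2.90 CPM. The labels do not give the deleted bases, so it is open whether the counts that were left lie inside or outside the deletions. YBR090C lies outside the fixed rule and was taken for its overlap with NHP6B.

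**Figure D1:**
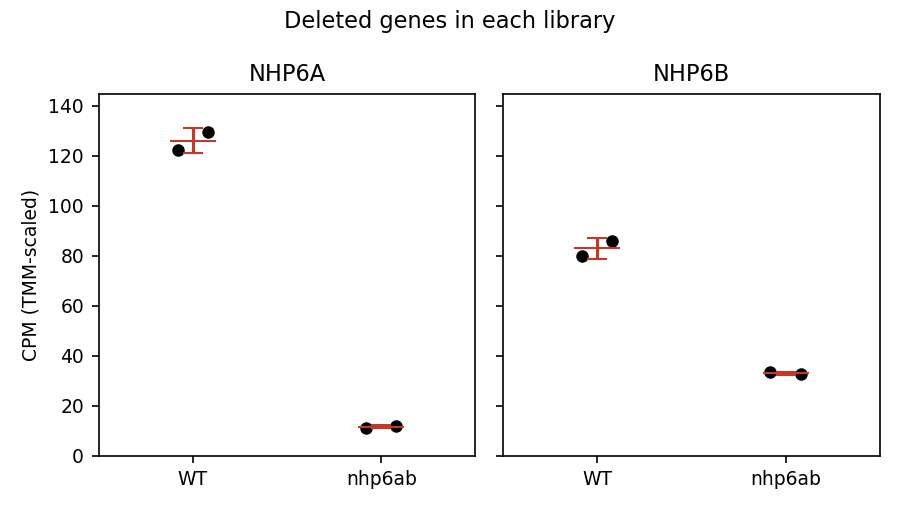
CPM of NHP6A (left) and NHP6B (right) in each library; black points are single libraries, and red bars are the mean ± SD of the 2 libraries of a strain. NHP6A lies between 11.1 and 12 CPM in nhp6ab and NHP6B between 32.6 and 33.4 CPM, all below the wild-type libraries.

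The question of the comparison is how the transcriptome of the nhp6ab strain differs from that of wild-type cells. In nhp6ab, the lists of ribosomal proteins, of amino acid synthesis under Gcn4 and of glycolysis were lower than in the wild type, as were single genes such as CHO2, OPI3 and HSP26. With an estimated correlation none of these lists was called (adjusted p = 0.70, 0.75 and 0.75). With 2 residual degrees of freedom, that form of the test has little power. Genes more than 2-fold higher included the histone genes HTA1 and HHF1, PCL1, which encodes a G1 cyclin, and MPC3, which encodes a subunit of the mitochondrial pyruvate carrier. With TMM scaling, large decreases outnumbered large increases. Of the 6422 genes, 1576 were higher and 1606 lower in nhp6ab at an adjusted p under 0.05 in edgeR's quasi-likelihood test, which is 49.5% of the genes tested. At a change of at least 2-fold, 88 were higher and 197 lower, and 3625 genes had an unadjusted p under 0.05. With library size alone 309 genes changed at least 2-fold, and their split by direction was not taken. With library size alone the median of all genes moved to 0.22 on the log2 scale and 79.1% of called genes were higher (3023 higher and 800 lower) against 49.5%, and on log2(TPM + 1) the median was 0.283, so the direction of small changes holds only relative to the scaling. In each list, as many or more members were called higher, and as many or fewer lower, with library size alone and on the TPM scale. Among genes named below as lower, those that lost their call with both included SMC3, ISW1, RSC4, VPS75, HTA2, HHT2, HHF2, COS10, INO4 and OPI1. Those that lost it on the TPM scale alone included HTB2, HSP10, CLB1, INO1, ZIP1, NOG1, HMO1, PLM2, ZRT1 and RPL8B. Without wild-type replicate 1 the higher genes numbered 901 and the lower genes 1063, and without wild-type replicate 2 the higher genes numbered 918.

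**Figure D2:**
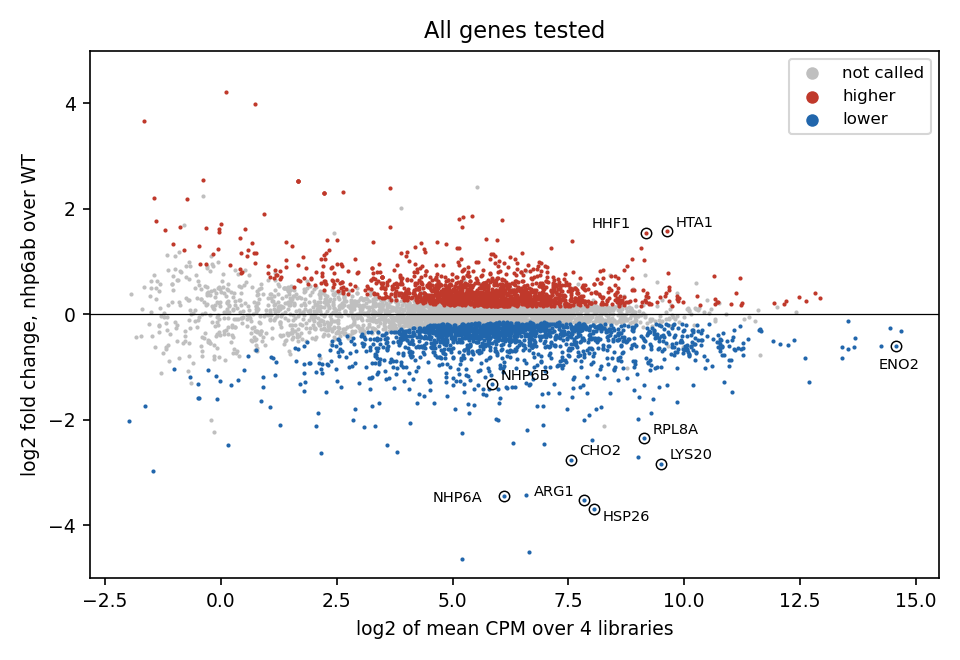
Log2 fold change of nhp6ab over wild type against the log2 of the mean CPM over the 4 libraries, 1 point per gene tested; red genes were called higher, blue genes lower and grey genes neither, and circled genes are named. The largest decreases among abundant genes include HSP26 at -3.69 and ARG1 at -3.52, and 5 genes lie beyond the axis limits of -5 and 5.

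The 12 largest increases by the fixed rule included metabolic genes, a cyclin gene and histone genes. CHA1 (YCL064C; chromosome III, 15798 to 16880), the serine and threonine deaminase, rose from 15.6 ± 1.6 to 54.4 ± 8.43 CPM (SD, n = 2 each; log2 fold change 1.81 ± 0.12 SE, adjusted p = 7.11e-05). MPC3 (YGR243W; chromosome VII, 977336 to 977776) rose from 18.3 ± 0.60 to 66.7 ± 1.81 CPM (1.87 ± 0.06, adjusted p = 5.41e-06). GAT2, which encodes a GATA-type zinc-finger protein, rose from 28.6 ± 0.07 to 76.9 ± 8.36 CPM (1.43 ± 0.08). PCL1 (YNL289W; chromosome XIV, 87897 to 88736) rose from 16.2 ± 0.17 to 58.3 ± 1.51 CPM (1.85 ± 0.06, adjusted p = 5.39e-06), and COS8, a subtelomeric gene, rose from 29.9 ± 1.15 to 104 ± 0.62 CPM (1.79 ± 0.06). The others were HTA1 and HHF1, described with the histones below, YLR112W (2.40), the unmatched identifier YGR259C (2.33), and 3 members of repeated families whose reads cannot be placed with certainty. Of these last, YHL050C had a log2 fold change of 1.65, YPR158C-C, a Ty gene, had 1.65, and YLL067C had 0 CPM in both wild-type libraries and 43.5 ± 19.0 CPM in nhp6ab.

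The 12 largest decreases held genes of amino acid and phospholipid synthesis, stress and the cell wall. CHO2 (YGR157W; chromosome VII, 802440 to 805049) and OPI3 (YJR073C; chromosome X, 572315 to 572935), which encode the methyltransferases that make phosphatidylcholine, fell from 327 ± 1.62 to 48.5 ± 3.88 CPM and from 214 ± 16.3 to 38.9 ± 0.29 CPM (SD, n = 2 each; log2 fold changes -2.76 ± 0.07 and -2.46 ± 0.07 SE). ARG1, the argininosuccinate synthetase, fell from 422 ± 42.8 to 36.8 ± 2.45 CPM (-3.52 ± 0.09, adjusted p = 2.61e-06), and LYS20, a homocitrate synthase with a near-identical copy in LYS21, fell from 1268 ± 13.0 to 178 ± 2.43 CPM (-2.83 ± 0.06, adjusted p = 1.05e-06). HSP26, a small heat shock protein, fell from 492 ± 64.8 to 38.0 ± 2.39 CPM (-3.69 ± 0.11), and YGP1, a secreted glycoprotein, from 891 ± 35.5 to 136 ± 5.22 CPM (-2.71 ± 0.07). TIR1, a cell wall mannoprotein, fell from 176 ± 54.0 to 16.4 ± 0.05 CPM (-3.42 ± 0.20). SIP4, a regulator of gluconeogenic genes, and RPI1, a putative regulator, fell by 2.62 and 2.48 on the log2 scale. The remaining 3 are uncertain: YPR053C overlaps NHP6A, and YER160C and YDR316W-B are Ty genes with many near-identical copies. YER160C had 38.2 ± 4.54 CPM in the wild type and 0.05 ± 0.07 CPM in nhp6ab, and YDR316W-B lost its call in DESeq2 (adjusted p = 0.282) and without wild-type replicate 1 (0.0589) or wild-type replicate 2 (0.068). Their fitted values moved to -8.59 and -3.52 without nhp6ab replicate 1 and to -12.95 and -15.29 without nhp6ab replicate 2.

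Genes for cytosolic ribosomal proteins were lower almost throughout. Of 137 measured, 131 fell and 1 rose (133 and 1 adjusted over the list alone), with a median log2 fold change of -0.60 and a list test adjusted p = 6.2e-29 with camera's preset correlation, against adjusted p = 0.70 with an estimated correlation. The strongest decreases by p were those of RPL8A, from 939 ± 41.3 to 185 ± 5.78 CPM (SD, n = 2 each; -2.34 ± 0.07 SE), RPS14B, from 161 ± 9.55 to 34.95 ± 2.67 CPM (-2.20 ± 0.08), RPL7B, from 201 ± 12.3 to 46.9 ± 3.53 CPM (-2.10 ± 0.08), and RPL22B, from 75.3 ± 2.59 to 26.3 ± 0.43 CPM (-1.52 ± 0.06). RPL8A and RPL7B each have a near-identical partner, RPL8B and RPL7A, and RPL7B overlaps SNR59, so their counts are uncertain. RPL8A, RPS14B, RPL7B and RPL22B are the less abundant copies of their pairs. Their partners fell less: RPL8B (-0.35), RPS14A (-0.13, not called), RPL7A (-0.48) and RPL22A (-0.66). Among 59 pairs the less abundant copy, by mean CPM over all libraries, fell more in 38. Because that mean includes nhp6ab, a copy that fell more was likelier to be ranked as less abundant, which raises this count. RPS22B rose (0.82 ± 0.06), whereas RPS22A, its more abundant partner, fell (-1.34). The partners were chosen after their values were seen. The list median was -0.39 with library size alone and -0.31 on the TPM scale, with 116 and 103 members still called lower. Genes for ribosome biogenesis moved less: 16 of 52 fell, 7 rose and 29 were not called (16 and 7 adjusted over the list alone; median -0.12, adjusted p = 0.13). SSF1 (-0.63 ± 0.07), NMD3 (-0.53 ± 0.06) and NOG1 (-0.43 ± 0.06) fell and IMP4 (0.63 ± 0.06) rose. The list median turned to 0.10 with library size alone (14 higher and 5 lower) and 0.17 on the TPM scale (19 and 2). The list was called lower without nhp6ab replicate 2 (adjusted p = 0.0052), and without wild-type replicate 1 or 2 the members that fell numbered 9 and those that rose 2 or 3.

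Genes of amino acid synthesis controlled by Gcn4, the activator of that pathway, fell as a list. Of 40 measured, 30 fell and 2 rose (32 and 2 adjusted over the list alone; median -0.59, adjusted p = 3.2e-09, adjusted p = 0.75 with an estimated correlation). Beside ARG1 and LYS20, the lysine genes LYS9 and LYS1 fell from 977 ± 46.5 to 265 ± 12 CPM and from 285 ± 10.5 to 96.4 ± 5.94 CPM (SD, n = 2 each; -1.88 ± 0.07 and -1.56 ± 0.07 SE). GCN4 itself (0.34) and ILV3 (0.26) were the 2 members that rose. The members that rose numbered 1 without wild-type replicate 1, where ILV3 was not called (adjusted p = 0.0719), and 5 without nhp6ab replicate 2. In the list of sulfur amino acid genes, 13 of 26 fell and 4 rose, also when adjusted over the list alone, and the list was not called (median -0.22, adjusted p = 0.074). SAM2, an S-adenosylmethionine synthetase, fell from 428 ± 14.9 to 123 ± 0.79 CPM (-1.80 ± 0.06), and MET14 (-1.35 ± 0.07), STR3 (-1.26 ± 0.09) and CYS4 (-1.02 ± 0.06) fell with it. The sulfur list was called lower with library size alone (adjusted p = 0.0077, with 9 members higher and 10 lower), on the TPM scale (0.0025, with 10 higher, 10 lower and a median of 0.08) and without nhp6ab replicate 1 (0.047). Of 20 purine and one-carbon genes 4 rose and 3 fell, also when adjusted over the list alone (median 0.39, adjusted p = 0.54). IMD3 rose (0.67 ± 0.09), whereas its paralog IMD4 (-0.72 ± 0.07), which overlaps SNR54 and is uncertain, and PHO3 (-0.62 ± 0.06), an acid phosphatase gene, fell. The purine list was called higher without nhp6ab replicate 2 (adjusted p = 0.00078, with 14 members higher), its median was -0.05 without nhp6ab replicate 1, with 7 members lower, and 1 member rose without wild-type replicate 1 or 2. With a replicate term 11 members were called higher and 3 lower, and with library size alone 11 and 2. GCV3 (0.75 ± 0.15) rose but lost its call without wild-type replicate 1 (adjusted p = 0.081) or wild-type replicate 2 (0.0754).

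Genes of glycolysis and fermentation, among the most abundant transcripts of the cell, fell in 13 of 17 cases and rose in 2 (13 and 2 adjusted over the list alone; median -0.59, adjusted p = 0.0018, adjusted p = 0.75 with an estimated correlation). ENO2, an enolase, fell from 29121 ± 642 to 19284 ± 408 CPM (SD, n = 2 each; -0.59 ± 0.04 SE) and GPM1, the phosphoglycerate mutase, from 13913 ± 509 to 7828 ± 383 CPM (-0.83 ± 0.05). TDH1 (-1.48 ± 0.08) and TDH2 (-1.28 ± 0.06), for glyceraldehyde-3-phosphate dehydrogenase, fell further, although TDH2 shares near-identical sequence with TDH3. TPI1 (0.32) and PGI1 (0.22) rose, the latter without a call when wild-type replicate 1 (adjusted p = 0.0937) or nhp6ab replicate 1 (0.0509) was left out. The 10 most abundant genes held 17.6 and 17.8% of counts in the wild type and 14.9 and 14.6% in nhp6ab. Of 47 genes for the respiratory chain and the TCA cycle, 22 fell and 4 rose (22 and 4 adjusted over the list alone; median -0.16, adjusted p = 0.019, adjusted p = 0.75 with an estimated correlation). CYC1 (-1.01 ± 0.09), COX4 (-0.61 ± 0.06), ATP17 (-0.57 ± 0.06) and CYC7 (-0.53 ± 0.06) fell, and COR1 (0.50), ATP1 (0.43), KGD1 (0.33) and SDH1 (0.29) rose, KGD1 and SDH1 without a call when wild-type replicate 2 was left out (adjusted p = 0.0649 and 0.104). This list lost its call without nhp6ab replicate 2 (adjusted p = 0.059), and its median turned to 0.05 with library size alone and 0.13 on the TPM scale, with adjusted p = 0.076 and 0.16. The balance of calls reversed there, with 17 members higher and 11 lower with library size alone and 22 and 4 on the TPM scale.

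Of 32 genes of the general stress response, 17 fell and 8 rose (18 and 9 adjusted over the list alone; median -0.28, adjusted p = 0.035, adjusted p = 0.70 with an estimated correlation). HSP26, YGP1, GCY1 (-1.74 ± 0.09), a glycerol dehydrogenase, and HOR7 (-1.35 ± 0.06) were among those that fell. The stress list lost its call without nhp6ab replicate 2, where its median was -0.363. On the TPM scale its median turned to 0.01 (12 higher and 14 lower), below the median of 0.283 of all genes. The list test still called it lower there (adjusted p = 0.00011) and with library size alone (0.00084). Heat shock chaperones went both ways: 10 of 23 rose and 4 fell (10 and 6 adjusted over the list alone; median 0.09, adjusted p = 0.73). HSP78, a mitochondrial chaperone, fell from 962 ± 34.6 to 314 ± 18.3 CPM (SD, n = 2 each; -1.61 ± 0.07 SE) and HSP10 fell (-0.40 ± 0.06), whereas the J-proteins SIS1 (0.72 ± 0.07) and MDJ1 (0.69 ± 0.08) rose. Of the chaperones 3 rose and 2 fell without wild-type replicate 1, 2 rose and 2 fell without wild-type replicate 2, and 5 rose and 9 fell without nhp6ab replicate 1, where the median was -0.04. Without nhp6ab replicate 2, 13 rose and 4 fell (median 0.21), and with library size alone 13 were called higher and 3 lower. Of 32 proteasome genes 6 rose and 3 fell (4 and 3 adjusted over the list alone; median 0.05, adjusted p = 0.55), with PUP1 (0.46 ± 0.07) and PUP2 (0.32 ± 0.06) higher and RPN4, the activator of these genes, lower (-0.51 ± 0.07). The proteasome genes that rose numbered 3 without wild-type replicate 1 or nhp6ab replicate 1 and 2 without wild-type replicate 2. With library size alone 23 of them were called higher and 1 lower (median 0.26, list test adjusted p = 0.081), and on the TPM scale 26 and 1. Of 16 DNA damage genes 5 fell and 3 rose, also when adjusted over the list alone (adjusted p = 0.92). RNR3 (-0.79 ± 0.11) and PLM2 (-0.53 ± 0.09) fell and RAD16 (0.30 ± 0.05) rose, and the median of 0.01 had the opposite sign to the mean of -0.08 and to the list test. Without wild-type replicate 1 or 2 the DNA damage genes that rose numbered 1, and without nhp6ab replicate 1 the median was -0.01. They were called higher in 9 cases and lower in 2 with library size alone (median 0.23), and in 10 and 2 on the TPM scale (median 0.29).

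The phosphate and iron regulons were called lower as lists. In the phosphate regulon 10 of 16 fell and 2 rose (10 and 2 adjusted over the list alone; median -0.46, adjusted p = 0.017, adjusted p = 0.75 with an estimated correlation). VTC3, a subunit of the polyphosphate polymerase, fell from 149 ± 7.58 to 63.8 ± 0.44 CPM (SD, n = 2 each; -1.23 ± 0.06 SE), VTC4 fell by 0.81 and VTC2 by 0.59 on the log2 scale, and PHO12, whose reads may be shared with PHO11, fell (-1.48 ± 0.07). PHO8 (0.29) and PHO5 (0.24) rose, and of these 0 were called without wild-type replicate 1 (adjusted p = 0.0899 and 0.118) and 1 without wild-type replicate 2 or nhp6ab replicate 2. In the iron regulon 14 of 24 fell and 2 rose (14 and 4 adjusted over the list alone; median -0.29, adjusted p = 0.035, adjusted p = 0.70 with an estimated correlation). The cell wall mannoproteins FIT1 (-2.0 ± 0.15), FIT3 (-1.49 ± 0.06) and FIT2 (-1.42 ± 0.10) fell, and CCC2, a copper transporter, rose (1.05 ± 0.06), as did FRE5 (0.64). The iron list lost its call without nhp6ab replicate 2, where its median was -0.199. On the TPM scale 7 of its members were higher and 5 lower, with a median of 0.00193. The list test still called it lower there (adjusted p = 0.0055) and with library size alone (0.0077). Of 14 copper and zinc genes 3 rose and 3 fell, also when adjusted over the list alone (median -0.03, adjusted p = 0.75). FRE7 (-1.40 ± 0.10), CTR1 (-1.04 ± 0.16) and ZRT1 (-0.47) fell, the last without a call on the TPM scale (adjusted p = 0.101). CUP1-1 and CUP1-2, near-identical copies with the same values that also overlap other genes, rose (0.63 ± 0.08 for each), as did ZPS1 (0.29), which lost its call in DESeq2 (adjusted p = 0.104) and without wild-type replicate 1 (0.133), wild-type replicate 2 (0.127) or nhp6ab replicate 2 (0.103). The median was 0.18 with library size alone (6 higher and 3 lower) and 0.24 on the TPM scale (8 and 2).

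Hexose transporters for glucose uptake were split. Of 17 measured 5 rose and 5 fell (5 and 6 adjusted over the list alone; median -0.04, adjusted p = 0.84). HXT3 fell from 1400 ± 51.3 to 442 ± 60.7 CPM (SD, n = 2 each; -1.66 ± 0.10 SE), HXT7, a near-identical copy of HXT6, from 813 ± 33.6 to 206 ± 4.31 CPM (-1.98 ± 0.06), and HXT1 fell (-0.96 ± 0.07), whereas the glucose sensor SNF3 rose (0.57 ± 0.07). The median of the transporters was 0.17 with library size alone (7 higher and 3 lower) and 0.21 on the TPM scale (8 and 3), and 3 fell without wild-type replicate 1. Of 27 glucose-repressed genes 9 rose and 6 fell (11 and 8 adjusted over the list alone; adjusted p = 0.78), and the median of 0.24 had the opposite sign to the mean of -0.01. Without wild-type replicate 1 or 2 the members that rose numbered 4, and with library size alone 13 were higher and 3 lower. HAP4 (0.74 ± 0.07) and GUT2 (0.61 ± 0.07) rose, and SUC2, the invertase, fell from 552 ± 21.1 to 271 ± 8.63 CPM (-1.02 ± 0.06). Of 8 galactose genes 4 rose and 1, GCY1, fell, also when adjusted over the list alone (median 0.25, adjusted p = 0.45). GAL10 (0.80 ± 0.08), GAL4 (0.38 ± 0.07), both overlapping non-coding genes and so uncertain, and GAL80 (0.27 ± 0.05) rose. Without wild-type replicate 1, 2 galactose genes rose and GAL4 was not called (adjusted p = 0.0517). Of 25 ergosterol genes 9 fell and 6 rose, also when adjusted over the list alone (adjusted p = 0.75), and the median of 0.04 had the opposite sign to the mean of -0.10 and to the list test. ERG3 (-1.0 ± 0.07), ERG5 (-0.67 ± 0.08), ERG25 (-0.67 ± 0.06) and ERG11 (-0.50 ± 0.06) fell. Ergosterol genes that rose numbered 1 without wild-type replicate 1, 2 without wild-type replicate 2 and 3 without nhp6ab replicate 1, where the median was -0.00746. On the TPM scale 15 were higher and 4 lower (median 0.33), and with library size alone 14 and 5 (median 0.25). Of 24 anaerobic and seripauperin genes 6 fell and 2 rose, also when adjusted over the list alone (median -0.34, adjusted p = 0.073), and TIR3 (-1.52 ± 0.12) and DAN1 (-1.38 ± 0.09) fell with TIR1. PAU3 was lower too (-1.39 ± 0.22), in a family with near-identical copies. The anaerobic list was called lower with library size alone (adjusted p = 0.0023), on the TPM scale (0.0011), without wild-type replicate 2 (0.046) and without nhp6ab replicate 1 (0.04).

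**Figure D3:**
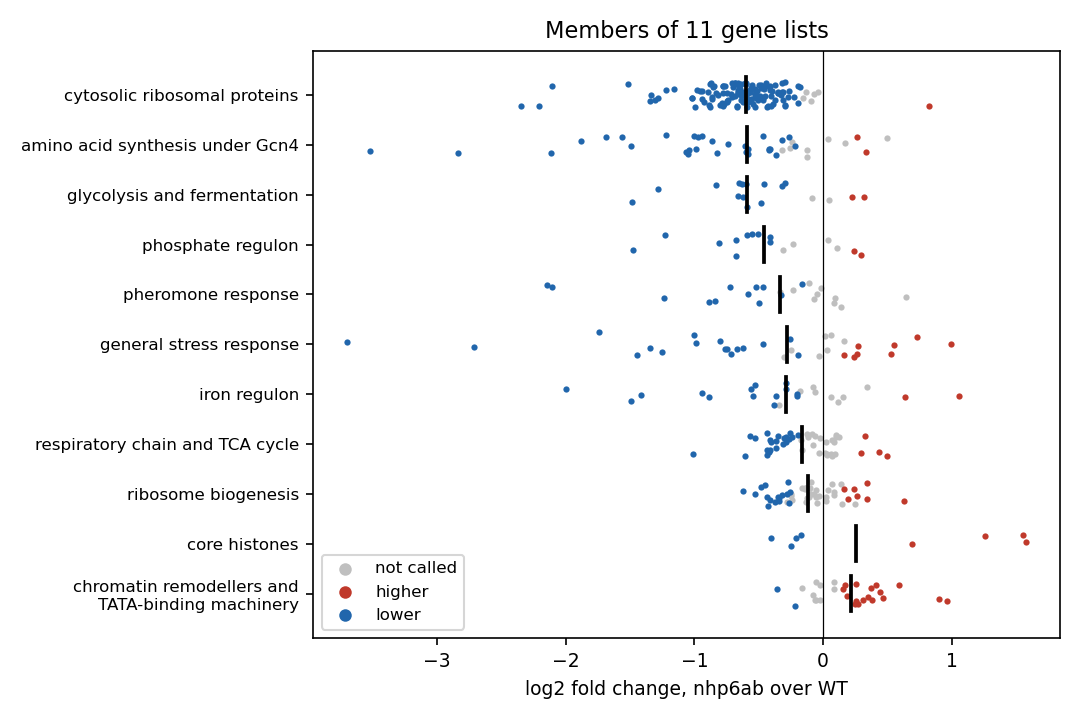
Log2 fold change of nhp6ab over wild type for each measured member of 11 gene lists; red members were called higher, blue members lower and grey members neither, and the black bar is the median of the list. The medians run from -0.60 for ribosomal proteins to 0.26 for core histones, and the medians of the respiratory, stress, iron and ribosome biogenesis lists turn above 0 on the TPM scale, as do those of the respiratory and ribosome biogenesis lists with library size alone. The stress and iron lists were still called lower on the TPM scale.

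The core histone genes divided by locus. Yeast has each core histone in a pair of genes, arranged as divergent couples. At HTA1-HTB1 (chromosome IV, 914317 to 915928), HTA1 rose from 399 ± 28.0 to 1189 ± 7.23 CPM (SD, n = 2 each; log2 fold change 1.57 ± 0.07 SE, adjusted p = 1.11e-05) and HTB1 from 233 ± 9.47 to 376 ± 8.18 CPM (0.69 ± 0.06). At HHT1-HHF1 (chromosome II, 255373 to 256741), HHF1 rose from 295 ± 20 to 862 ± 29.8 CPM (1.55 ± 0.07) and HHT1 from 316 ± 21.3 to 758 ± 24.8 CPM (1.26 ± 0.07). The genes of the other couples, HTA2-HTB2 and HHT2-HHF2, were called lower by less: HTB2 by -0.41 ± 0.06, HTA2 by -0.25 ± 0.06, HHF2 by -0.21 ± 0.06 and HHT2 by -0.18 ± 0.06. With library size alone HHF2 and HHT2 lay at 0.00493 and 0.04 and HTA2 at -0.04, none of them called, and on the TPM scale HTA2, HHT2 and HHF2 lay at 0.04, 0.12 and 0.09. HHF2 lost its call without any of the 4 libraries (adjusted p = 0.0529 to 0.0894), HHT2 without wild-type replicate 1 (0.167), wild-type replicate 2 (0.0826) or nhp6ab replicate 1 (0.158) and with a replicate term (0.0601), and HTA2 without wild-type replicate 1 (0.0651). HHF1 and HHF2 share near-identical sequence, so their reads are divided with some uncertainty. With 4 members up and 4 down (the same counts adjusted over the list alone), the list of 8 was not called (median 0.26, adjusted p = 0.54).

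**Figure D4:**
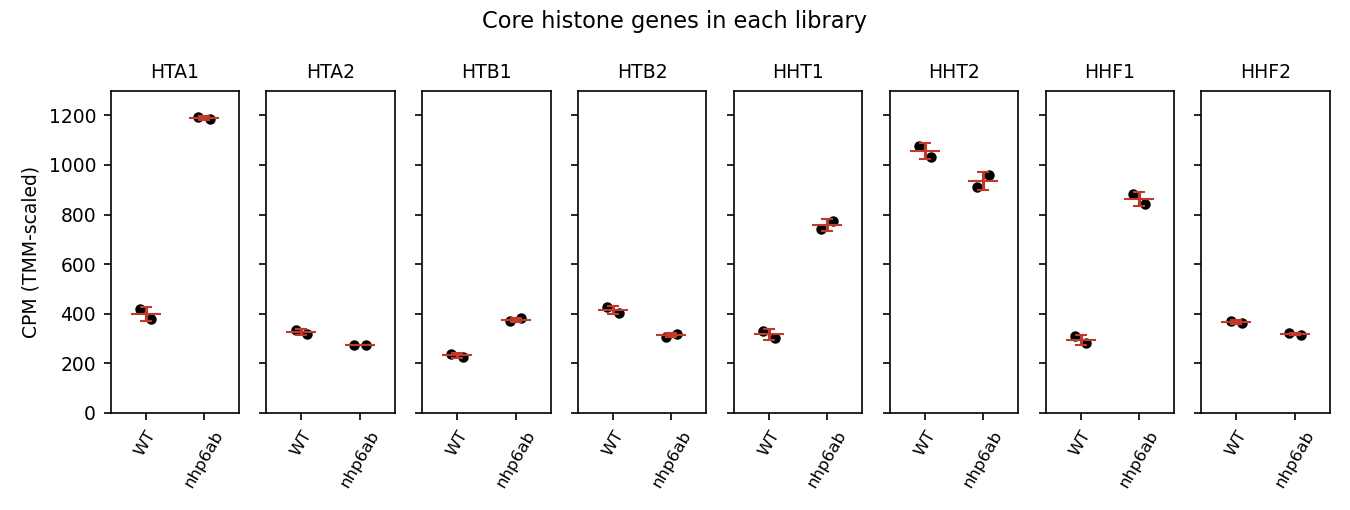
CPM of the 8 core histone genes in each library; black points are single libraries, and red bars are the mean ± SD of the 2 libraries of a strain. HTA1 reaches 1189 CPM in nhp6ab against 399 in the wild type, and HHF1 reaches 862 against 295, while the small decreases of HTA2, HHT2 and HHF2 turn above 0 on the TPM scale, and those of HHT2 and HHF2 also with library size alone.

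Genes for chromatin remodellers and the TATA-binding machinery rose as a list. Of 28 measured, 17 rose and 2, ISW1 (-0.36) and RSC4 (-0.22), fell (17 and 3 adjusted over the list alone; median 0.22, adjusted p = 0.017, adjusted p = 0.70 with an estimated correlation). BUR6, a subunit of the NC2 regulator of TATA-binding protein, rose from 81.7 ± 0.26 to 159 ± 0.25 CPM (SD, n = 2 each; 0.96 ± 0.05 SE) and SWR1, the H2A.Z exchange ATPase, from 92.1 ± 1.40 to 172 ± 9.62 CPM (0.90 ± 0.06). TOA1 (0.44 ± 0.05) and SNF6 (0.37 ± 0.05) were among the others that rose. Without wild-type replicate 2 the remodeller genes that rose numbered 9. ISW1 was not called with library size alone (-0.15, adjusted p = 0.108) or on the TPM scale (-0.06, adjusted p = 0.501). RSC4 lay at 0.07 on the TPM scale and lost its call with library size alone (adjusted p = 0.949) and without wild-type replicate 1 (0.0914), wild-type replicate 2 (0.13) or nhp6ab replicate 1 (0.0539). Of 19 histone chaperone genes, FACT subunits included, 4 rose and 3 fell (3 and 3 adjusted over the list alone; median -0.04, adjusted p = 0.84). ASF1 rose (0.35 ± 0.05) and VPS75, which overlaps CWC25 and is uncertain, fell (-0.30 ± 0.05). VPS75 was not called with library size alone (adjusted p = 0.227) or on the TPM scale (0.917). SPT16 and POB3 had log2 fold changes of -0.04 and -0.03 and were not called, but with library size alone both were called higher (0.17 and 0.19, adjusted p = 0.0356 and 0.0262), and the list had 10 members higher and 0 lower (median 0.17). The chaperone genes that rose numbered 2 without wild-type replicate 1 or nhp6ab replicate 1 and 1 without wild-type replicate 2, where CAC2 (0.28) was not called (adjusted p = 0.0566), and 1 fell without wild-type replicate 1 or nhp6ab replicate 1. All 5 genes for other HMG-box proteins were called: ROX1 (0.93 ± 0.10), IXR1 (0.44 ± 0.07), NHP10 (0.21 ± 0.06) and ABF2 (0.21) rose and HMO1 (-0.42 ± 0.05) fell (4 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.29). NHP10 lost its call in DESeq2 (adjusted p = 0.0514) and without wild-type replicate 1 (0.0597), wild-type replicate 2 (0.124) or nhp6ab replicate 1 (0.0633), and ABF2 without wild-type replicate 1 (0.0681), wild-type replicate 2 (0.118) or nhp6ab replicate 2 (0.0811). In this and the other lists SPT16, POB3, ABF2, ZRT1, ZPS1 and the members named for going against their list were chosen after their values were seen.

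Of 12 loci studied before for Nhp6 or FACT, 4 rose and 4 fell, also when adjusted over the list alone (median -0.11, adjusted p = 0.84). CHA1, CUP1-1, FLO11 (0.48 ± 0.07) and PHO5 (0.24 ± 0.07) rose. SUC2, CYC1, HO (-0.80 ± 0.12) and INO1 (-0.53 ± 0.09) fell. The others were not called: SER3, which overlaps SRG1, had -0.34 ± 0.19, DDR2 -0.31 ± 0.13, GAL1, which overlaps a non-coding gene, 0.28 ± 0.16 and HSP82 0.08 ± 0.07. PHO5 lost its call in DESeq2 (adjusted p = 0.0608) and without wild-type replicate 1 (0.118), wild-type replicate 2 (0.0593) or nhp6ab replicate 2 (0.102). SER3 gained one without nhp6ab replicate 1 (-0.71, adjusted p = 0.000357) and with a replicate term (-0.37, adjusted p = 0.00957), and DDR2 (-0.44, adjusted p = 0.0203) and HSP82 (0.18, adjusted p = 0.0299) did so without nhp6ab replicate 2. GAL1 and HSP82 were called higher with library size alone (0.49 and 0.29), where the list median was 0.10, and the median was 0.07 without nhp6ab replicate 2.

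The wild-type and nhp6ab libraries both had the transcripts of alpha cells. MF(ALPHA)1, the main alpha-factor gene, had 790 ± 23.0 CPM in the wild type and 889 ± 74.1 CPM in nhp6ab (SD, n = 2 each; adjusted p = 0.087), and it was called higher without nhp6ab replicate 1 (0.25, adjusted p = 0.0322) and with library size alone (0.39, adjusted p = 0.00406). MF(ALPHA)2 fell from 391 ± 45.6 to 104 ± 3.68 CPM (-1.92 ± 0.09 SE), SAG1, the alpha agglutinin, from 822 ± 58.6 to 396 ± 9.05 CPM (-1.05 ± 0.07) and STE3, the a-factor receptor, from 205 ± 10.4 to 126 ± 3.03 CPM (-0.71 ± 0.06). The alpha-specific list, with 3 of 4 lower (3 lower and 1 higher adjusted over the list alone), was not called (median -0.88, adjusted p = 0.094), but it was called lower with library size alone (0.0084) and on the TPM scale (0.0022). The 4 a-specific genes tested had strain means of up to 23.05 CPM, and 0 were called by edgeR, also when adjusted over the list alone, and 0 by DESeq2, with unadjusted p of at least 0.272 (median 0.14, list test adjusted p = 0.73). STE6 had a log2 fold change of 0.06 and BAR1 of 0.21. BAR1 was called without nhp6ab replicate 1 (0.40, adjusted p = 0.0467), and STE6 with library size alone (0.28, adjusted p = 0.0255). Pheromone response genes fell in 12 of 22 cases and the other 10 were not called (13 lower and 1 higher adjusted over the list alone; median -0.33, adjusted p = 0.0096, adjusted p = 0.77 with an estimated correlation). FIG1 (-2.15 ± 0.22), FUS2 (-1.23 ± 0.09), KAR4 (-0.89 ± 0.07) and AGA1 (-0.84 ± 0.08) were among those that fell. Of the pheromone genes 10 were lower and 3 higher with library size alone (median -0.12), and 8 and 5 on the TPM scale (median -0.03). Of 28 meiosis and sporulation genes 8 fell and 6 rose (8 and 7 adjusted over the list alone; median -0.07, adjusted p = 0.73). REC8 (1.38 ± 0.12) and IME2 (0.94 ± 0.13) rose, and SMK1 (-0.72 ± 0.09), which lies beside YPR053C, and ZIP1 (-0.61 ± 0.07) fell. The meiosis median was 0.14 with library size alone (10 higher and 7 lower) and 0.19 on the TPM scale (10 and 5).

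Cell cycle lists were not called by camera, although fry called the G1 and S phase genes higher (adjusted p = 0.018). Of 23 G1 and S phase genes 7 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.73), and the median of -0.00201 had the opposite sign to the mean of 0.10 and to the list test. Without wild-type replicate 1 or 2, 4 rose and 3 fell, 3 fell without nhp6ab replicate 2, and the median was 0.21 with library size alone (11 higher and 0 lower), 0.06 without wild-type replicate 2 and 0.03 without nhp6ab replicate 2. The G1 cyclins PCL1, CLN2 (0.59 ± 0.06) and CLN1 (0.52 ± 0.06) rose, and SMC3 fell (-0.38 ± 0.07). Of 15 G2 and M phase genes 8 rose and 2 fell, also when adjusted over the list alone (median 0.23, adjusted p = 0.13), with SWI5 (0.60 ± 0.07), BUD8 (0.50 ± 0.07) and ALK1 (0.43 ± 0.06) higher and CLB1 (-0.55 ± 0.09) lower. Of 17 daughter-cell and early G1 genes 9 fell and 3 rose (10 and 3 adjusted over the list alone; median -0.29, adjusted p = 0.24). HO, the mating-type endonuclease, fell from 21.8 ± 1.58 to 12.5 ± 1.85 CPM (SD, n = 2 each), RME1 (-0.70 ± 0.06 SE) and AMN1 (-0.56 ± 0.07) fell, and DSE1 (0.67 ± 0.09) and DSE2 (0.61 ± 0.08) rose. Of this list 5 fell without wild-type replicate 1, and on the TPM scale 5 were higher and 3 lower, with a median of 0.01. Of 22 cell wall genes 7 rose and 5 fell (9 and 5 adjusted over the list alone; median 0.16, adjusted p = 0.36), with CCW14 (0.84 ± 0.08), SED1 (0.69 ± 0.08) and FLO5 (0.65 ± 0.07) higher and GSC2, a glucan synthase, lower (-0.86 ± 0.05). With library size alone 14 cell wall genes were called higher and 2 lower, on the TPM scale 15 and 2, and the median was 0.04 without nhp6ab replicate 1.

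Of 8 genes used as selection markers 3 rose and 2 fell, where 49.5% of all genes tested were called. HIS3 rose from 105 ± 8.19 to 276 ± 72.0 CPM (SD, n = 2 each; 1.39 ± 0.16 SE), URA3 from 67.6 ± 0.51 to 130 ± 7.09 CPM (0.94 ± 0.06), and TRP1 by less (0.17 ± 0.06). The labels do not give the markers used for the deletions, so counts from a marker cassette are not excluded. LYS2 (-1.40 ± 0.08) and MET17 (-0.59 ± 0.06), which overlaps YLR302C and is uncertain, fell. ADE2 (0.75 ± 0.32), LEU2 (-0.14 ± 0.07) and CAN1 (0.11 ± 0.07) were not called, and the list of 8, with 3 higher and 2 lower, also when adjusted over the list alone, was not called (median 0.14, adjusted p = 0.75). TRP1 lost its call in DESeq2 (adjusted p = 0.147) and without wild-type replicate 1 (0.114), wild-type replicate 2 (0.162) or nhp6ab replicate 1 (0.173). ADE2 gained one without nhp6ab replicate 2 (1.22, adjusted p = 7.93e-06) and with a replicate term (0.63, adjusted p = 0.0152), and ADE2 and CAN1 did so with library size alone (0.95 and 0.32). By position, 58 of 200 measured genes within 20000 bases of a chromosome end rose and 35 fell (56 and 35 adjusted over the list alone; median 0.06, adjusted p = 0.41), with ERO1 lower (-1.06 ± 0.06), and 38 rose without wild-type replicate 2 whereas 95 were higher and 22 lower with library size alone. Of 1345 measured genes with a TATA box in the upstream 200 bases, 315 rose and 423 fell (324 and 430 adjusted over the list alone; median -0.04, adjusted p = 0.29). RTA1 (-2.45 ± 0.06) and YLL056C (-2.01 ± 0.06) were among those that fell. The genes with a TATA box that rose numbered 185 without wild-type replicate 1 and 194 without wild-type replicate 2, and their median was 0.17 with library size alone, where 590 were higher and 252 lower, and 0.24 on the TPM scale, with 670 and 202. The median log2 fold change per nuclear chromosome ran from -0.04 on chromosome VIII to 0.13 on chromosome I.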

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

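All alternatives were planned. Counts of higher, lower and at least 2-fold changed genes stayed within 1.5 times under DESeq2 size factors, upper quartile factors, TMM without ribosomal protein genes, DESeq2, limma-voom, a robust fit, unrounded counts and both filters, and 0 genes called in both fits had opposite signs there. With library size alone 3023 genes were higher and 800 lower, since the median of all genes moved to 0.22. On log2(TPM + 1), which also keeps no TMM factor, 3566 were higher and 617 lower, and on log2(TPM + 0.1) 3558 and 614. HHF2 changed sign to 0.00493 with library size alone and to 0.0862 and 0.0863 on the TPM scales, HHT2 to 0.0377, 0.118 and 0.118, and HTA2 to 0.0421 and 0.0422 on the TPM scales. Leaving out 1 library, with the lone sample assumed to vary like the other strain, gave 901 to 1462 higher genes, 1063 to 1557 lower genes and 261 to 314 genes changed at least 2-fold, fewest where a wild-type library was left out, and the cause was not tested. These fits called 1 to 2 lists higher and 6 to 10 lower. Of 35 lists, 0 were called higher and 0 lower with an estimated correlation, which had little power with 2 residual degrees of freedom. Fry called 4 higher and 14 lower, among them every list called by camera. The others higher were core histones (adjusted p = 0.029), G1 and S phase genes (0.018) and subtelomeric genes (0.018). The others lower were the glucose-repressed (0.015), copper and zinc (0.015), sulfur (0.017), alpha-specific (0.018), anaerobic (0.044) and TATA-box (0.0068) lists. Replicate numbers did not pair the libraries (correlation of deviations -0.06), and a replicate block gave 1626 higher and 1686 lower genes. Over 163 named genes and 11 alternatives, 1698 of 1793 values kept their call with its direction or stayed without a call. Of the others 63 lost and 24 gained a call, and 8 values of genes called in the main fit changed sign. Sign changes of genes without a call in both fits were not counted. In simulation at these depths and this spread, but with far fewer genes changed than were called here, 33 of 50 genes changed 1.3-fold were found. The share of depth in this was not tested.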

Other observations

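The gene groups in this part, and all tests but those of YBR090C, of the histone neighbours, of library size alone and of the matched lists, were chosen after the results were seen. Of 10 genes picked for phosphatidylcholine synthesis, its inositol supply and its control, CHO2 and OPI3 included, 10 fell in edgeR, with a median log2 fold change of -0.98, although INO4 (-0.21) and OPI1 (-0.19) turned to 0.00653 and 0.02 with library size alone and were not called by DESeq2 (adjusted p = 0.104 for each). INO4 lost its call without wild-type replicate 1 (adjusted p = 0.118), wild-type replicate 2 (0.0679) or nhp6ab replicate 2 (0.138), and OPI1 without wild-type replicate 1 (0.0815), wild-type replicate 2 (0.238) or nhp6ab replicate 1 (0.139). CHO1 (-1.02 ± 0.06 SE) and PSD1 (-0.92 ± 0.06), which act before the methylations, the inositol transporter ITR1 (-1.18 ± 0.06) and INO2 (-0.94 ± 0.12), the activator of these genes, were among them, and SAM2 makes the methyl donor. All 7 genes examined of lysine synthesis fell, from -0.97 (LYS4) to -2.83 (LYS20). In the COS family 6 of 10 genes rose, among them COS8, COS1 (1.40 ± 0.12) and COS7 (0.99 ± 0.07), although COS1 and COS7 have near-identical copies. COS10 (-0.26) fell, but it lay at 0.03 on the TPM scale and lost its call without wild-type replicate 2 (adjusted p = 0.0858) or nhp6ab replicate 1 (0.07).

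Adenine synthesis separated the nhp6ab libraries from each other. ADE2 had 994 CPM in nhp6ab replicate 1 and 440 CPM in replicate 2, against 417 and 438 CPM in the wild type, and ADE1 had 1049 and 586 CPM against 537 and 534 CPM. All 9 genes examined of the pathway were higher in nhp6ab replicate 1 than in replicate 2, with a median log2 difference of 0.73, and the wild-type libraries differed by a median of 0.00899. The Ty gene YER160C had 41.4 and 35 CPM in the wild type and 0 and 0.10 CPM in nhp6ab, and BUR6, which nearly doubled, lies 897 bases from it in the reference.

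NHP6B kept 39.8% of its wild-type CPM in a strain named for its loss. Wild-type cells in the cultures would leave the same share of both genes, and NHP6A kept 9.18%. If NHP6A reads had been given to NHP6B at the wild-type ratio of the genes, they would account for 7.62 of the 33.0 CPM seen. RSEM divides shared reads by estimate, so that ratio need not hold in nhp6ab, and the value sets no upper limit. Reads from YBR090C, which overlaps NHP6B, remain possible: YBR090C had 19.6 CPM in nhp6ab, which is below NHP6B but not by enough to settle it, and it kept 43.3% of its wild-type level. Transcription of a part of NHP6B left by the deletion may also remain, and the table, with 1 total per gene, does not show where in the gene the reads lie.

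HTA1-HTB1 and HHT1-HHF1 rose while the other histone couples did not. Reads moved between copies would leave the sum of both copies in place, but the sums rose by 1.01 for H2A, 0.84 for H4 and 0.30 for H3, the smallest. For H2B the sum moved by 0.0906. HTB1 and HTB2 were not marked as near-identical, but that mark needed at least 95% identity, so a shift of reads between them stays open. Extra copies of both segments would lift their neighbours, and the medians over the 10 nearest genes were 0.0862 and 0.0521, although a segment with the histone genes alone is not excluded. Loss of repression by the HIR complex, which also acts at HHT2-HHF2, would lift that couple, and its higher value was -0.18, or 0.12 on the TPM scale, where the median of all genes was 0.28. That couple is part of the pattern, so its values were known when this check was chosen. HIR1 itself was called lower (-0.29 ± 0.08 SE), and HIR3 (0.01) and HPC2 (0.03) were not called. HIR2, also tested, was not among the 3 histone chaperone genes called lower. With library size alone 0 histone chaperone genes were called lower. Why the couples differ stays open, and the loss of Nhp6 as a cause is untested.

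Ribosomal protein genes fell by a median of 0.60 on the log2 scale. With library size alone their median was -0.39 and 116 of 137 were still lower, which argues against scaling as the whole cause. Of 10000 random lists of other genes near in coding length and expression, 95% had medians between -0.12 and 0.01 and 0 lay as low as the list, although the matched genes had a median of 635 CPM against 894 CPM. A drop shared with ribosome biogenesis, as slower growth may bring, would need a larger change than the median of -0.12 in that list. Loss of Nhp6, any other difference between the strains and a difference in culture state all stay open, since this comparison cannot separate them.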
